A study of Mus musculus with 6 samples.

How the data were processed

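The series holds RNA-seq gene counts of mouse germinal vesicle (GV) oocytes, fully grown oocytes arrested before meiotic resumption, from 2 genotypes with 3 mice each. The genotype called DKO was null for Ring1, carried floxed Rnf2 alleles and had the Zp3-cre transgene, which is active in growing oocytes, so that both catalytic E3 ligases of Polycomb repressive complex 1 (PRC1) were targeted. The genotype called SKO was null for Ring1 and carried the floxed Rnf2 alleles without the transgene. Per the labels' protocols, 15 GV oocytes of 1 mouse were pooled for each library, the females were about 3 months old on a mixed strain background, and granulosa cells were stripped off by pipetting. Each library therefore came from its own animal. RNA was amplified with the Ovation kit before Illumina libraries were made, per the labels' protocols, so reads are not independent molecules, and the intervals and floors given here cover counting error only. The labels describe the samples as repeat analyses of earlier ones.

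The authors deposited 1 table of raw read counts per Entrez gene, with no normalization, and a column of gene lengths in bases. STAR 2.5.0a and the builds GRCm38 and mm10 are named in the submitters' processing notes. The counter, the gene annotation, the handling of strand and the treatment of reads with several alignments are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart. Some overlapping genes held near-identical counts in every library: 41 tested genes formed 8 such clusters (overlapping coordinates, at least 30 counts in all, and counts within 5% or 2 counts of each other in every library). Of these genes, 31 were called higher and belonged to 3 clusters, so a read can stand behind several called genes. Column names matched the sample titles, and 0 further columns of samples were left unused.

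Entrez identifiers were matched to the RefSeq annotation of GRCm38, from which symbols and coordinates were taken. Of 24421 identifiers, 24387 matched, and the 34 others held at most 0.087% of the counts of any library. No count was detected in any library for 4102 genes.

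Counts per library ranged from 15521975 to 26652745, and the floor of 3 counts corresponded to 0.113 to 0.193 CPM (counts scaled to a common library size). Tests were run in R 4.3.3 with edgeR 4.0.16: filterByExpr with default settings (minimum count 10, minimum total 15) kept 14845 genes, libraries were scaled with TMM, and the 2 genotypes were compared with the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p under 0.05 were called. Every fold change is DKO over SKO on the log2 scale. Its standard error was taken from the F statistic and can be too small where a group has few counts. CPM values are given on TMM-scaled library sizes as mean ± SD over 3 mice. For a gene with 0 counts in all 3 SKO libraries, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its exact 95% Poisson interval.

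Before the data were examined, 19 gene lists were fixed. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation was run beside it, and fry, which tests whether a list changes at all and not whether it changes more than other genes. Of 895 list entries, 7 were not found in the table. Some genes are entered in several lists, so the list results are not independent of each other. The lists were Polycomb subunits of PRC1 and of PRC2, Hox genes, developmental transcription factors, cell cycle inhibitors, signalling ligands and antagonists, germline and meiosis genes, oocyte growth and maternal effect genes, meiotic maturation and spindle genes, DNA methylation machinery, imprinted genes that depend on H3K27me3, canonical imprinted genes, early zygotic genes, p53 targets and cell death genes, oxidative phosphorylation, cytosolic ribosomal proteins, and markers of granulosa and cumulus cells, of theca, stroma and endothelium, and of blood and immune cells.

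The rule for named genes was fixed at the same time. It takes Rnf2 and Ring1, then the 12 largest rises and 12 largest falls among called genes with an average of at least 2 log2 CPM and no overlap between the groups, leaving out clone names and pseudogenes, then up to 4 called members of each list with the smallest adjusted p. The 3 most abundant tested members of each marker list are given too. Of 93 named genes that were tested, 14 overlap another tested gene and 0 belong to a cluster of near-identical counts. Passing over clone names removed 1 rise and 3 falls. Chance alone separates 3 samples from 3 in 10% of genes.

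The code was tested on simulated counts for the comparison of DKO with SKO, drawn for 14845 genes from the SKO means and the real library sizes. Of the genes above 1 CPM in SKO, 200 were changed. At 4-fold, edgeR recovered 90% of 100 changed genes, and at 2-fold it recovered 40% of 100. Of its calls, 2.99% were unchanged genes. In DESeq2 1.42.0 that share was 16% and in limma voom 2.34%. Camera called the 1 list seeded with changed genes and 0 of 18 random lists. Simulated genes were drawn independently of each other, so the list result does not cover lists of correlated genes. The correlation estimated for the real oocyte list, for example, was 0.178. Recovery was not tested for genes below 1 CPM in SKO, where 1145 of the real rises started.

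The alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, the DESeq2 Wald test, limma voom with sample quality weights, no filter, a stricter filter (5 CPM in 3 samples), the replicate number as a block, leaving out each library, an adjusted p under 0.01, and for lists an estimated correlation, fry and a prior count of 0.5. Chosen after seeing the data were thinning every library to the smallest, removing the trend of each library with GC content and gene length (loess with a span of 0.3 on genes above 2 log2 CPM, GC content from the longest annotated transcript, for the 94.6% of tested genes with a GC value), and counting overlapping genes with near-identical counts once. Plots were drawn with matplotlib 3.10.9.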

Results

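Gene expression was measured by RNA-seq in GV oocytes of mice lacking Ring1 alone (SKO) and of mice lacking Ring1 with oocyte deletion of Rnf2 (DKO), with 3 libraries per genotype and 15 oocytes of a single animal in each. Ring1 is null in both genotypes, so the comparison addresses the deletion of the core PRC1 member Rnf2 during oocyte growth on a Ring1-null background. Only DKO carried the Zp3-cre transgene, so an effect of the transgene itself cannot be told apart from that of the deletion. Total counts were 15521975, 19813804 and 26652745 in DKO replicates 1 to 3, and 25470098, 22990699 and 26437540 in SKO replicates 1 to 3. Log2 CPM correlated at 0.942 to 0.962 between DKO libraries, at 0.973 to 0.977 between SKO libraries and at 0.865 to 0.898 between genotypes (Pearson r across genes, which are not independent replicates). The first principal component held 71.5% of the variance and the second 10.7%.

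Rnf2, the targeted E3 ligase gene (chromosome 1, 151469398 to 151500991, GRCm38, RefSeq annotation), fell in DKO oocytes. It measured 36.6 ± 17.5 CPM in DKO and 190 ± 11.8 CPM in SKO (SD, n = 3 mice each), a log2 fold change of -2.38 (SE 0.30, edgeR quasi-likelihood test, adjusted p = 0.000349). The counts were 989, 654 and 589 in the DKO libraries and 5041, 3901 and 4563 in the SKO libraries. Whether the counted exons include the deleted part is not given in the sources used here. Ring1 (chromosome 17, 34020792 to 34024680), null in both genotypes, had 19 counts over the DKO libraries and 10 over the SKO libraries and was below the filter for testing.

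Deletion of Rnf2 on this background went with more rises than falls. Of 14845 genes tested, 2567 were higher in DKO and 1100 were lower, together 24.7% of the genes (edgeR quasi-likelihood test, adjusted p under 0.05). Rises were large and started from low levels: 2267 of them (88.3%) reached 2-fold, their median log2 fold change was 2.59, and the median gene went from 1.42 CPM in SKO to 10.7 CPM in DKO. Falls were smaller and affected abundant transcripts: 426 (38.7%) reached 2-fold, the median was -0.89, and the median gene went from 71.3 to 39 CPM. The risen genes held 2.89 ± 0.037% of counts in SKO and 8.48 ± 0.85% in DKO (SD, n = 3), and the fallen genes held 19.5 ± 0.18% and 12.8 ± 1.2%.

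The split depended on the baseline. Among genes that pass the expression filter on the SKO libraries alone, 839 of 4287 at 1 to 10 CPM in SKO rose and 112 fell, and of 2374 genes over 100 CPM, 53 rose and 446 fell. At 0.1 to 1 CPM, 114 of 475 such genes rose and 4 fell, where low counts leave little room to detect a fall. A further 1668 genes in that range and 351 at up to 0.1 CPM entered only with the help of DKO libraries, so their 684 and 347 rises are in part fixed by the filter. Protein-coding genes accounted for 2481 rises and 1029 falls, and long noncoding RNAs for 71 and 53. Rises made up 70% of the calls with TMM and 83% with library totals alone, which gave 2905 rises and 596 falls and moved the median of all genes from 0.04 to 0.20. With the trend with GC content and gene length removed, rises made up 56.4% of the calls (2500 rises and 1933 falls among 14048 genes with a GC value). The count of falls was 516 without SKO replicate 1, 464 without SKO replicate 2 and 434 without SKO replicate 3. It was 852, 1318 and 1501 without DKO replicates 1, 2 and 3. DKO libraries differed more from each other than SKO libraries did, while the test assumes the same spread in both genotypes.

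**Figure D1:**
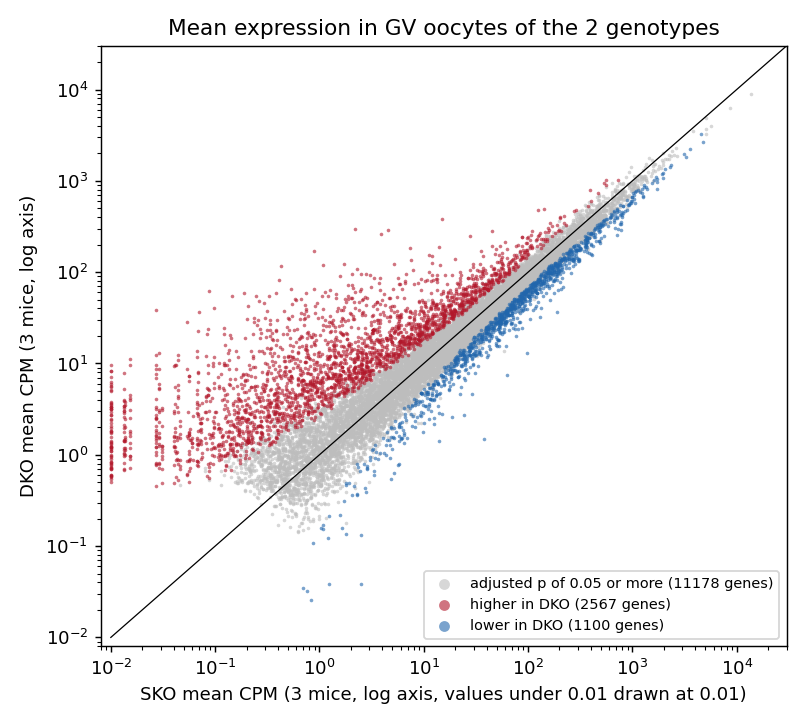
Mean CPM of each tested gene in SKO (horizontal, log axis) and DKO (vertical, log axis) oocytes, 3 mice per genotype, with the line of equality. Red points are the 2567 genes higher in DKO, spread over the low end of the SKO axis, and blue points are the 1100 lower genes, gathered at higher levels.

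The largest rises were genes close to silent in SKO oocytes. Cldn2, a tight junction protein gene, had 0 SKO counts and 9.62 ± 5.49 CPM in DKO, at least 211-fold higher (adjusted p = 0.000279, edgeR). The imprinted noncoding RNA H19 and the kidney progenitor factor Six2 also had 0 SKO counts and were at least 195-fold and 193-fold higher. Slc1a2, a glutamate transporter gene, had 2 SKO counts and a ratio of 1337 (95% interval 370 to 11050). Amigo2 rose from 0.0883 to 61.9 ± 25.5 CPM (log2 fold change 9.42, SE 0.60). The chloride channel gene Clic6 rose to 37.1 ± 7.57 CPM (8.93, SE 0.43) and the growth factor gene Bmp2 to 28.1 ± 5.71 CPM (8.83, SE 0.51). These 3 genes had 6, 5 and 4 SKO counts, so these standard errors understate the uncertainty. The DESeq2 Wald test gave larger ones of 0.676, 0.704 and 0.78. The homeobox gene Irx2 reached 41 ± 12 CPM and Zfp711 54.4 ± 12.8 CPM. Sall1, Dmrt3 and the kinase gene Nrk had 1 or 2 SKO counts, with ratios of 449 (124 to 3712), 400.5 (110.5 to 3314) and 597 (107 to 23620). Without DKO replicate 1 the log2 fold change of Nrk went from 8.93 to 7.35 and that of Dmrt3 from 8.53 to 7.50. With 0 SKO counts left, Nrk had 10.76 without SKO replicate 2 and Dmrt3 had 11.09 without SKO replicate 1. Amigo2 had 10.38 without SKO replicate 2 and 8.83 without SKO replicate 3, and Clic6 had 9.56 without SKO replicate 3. Adjusted p-values of these 12 genes lay between 1.35e-06 and 0.000722.

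The largest falls were smaller in fold. The integrin gene Itgb4 went from 13.9 ± 6.02 CPM in SKO to 1.4 ± 0.91 CPM in DKO (log2 fold change -3.29, SE 0.52, adjusted p = 0.00145, edgeR), and the claudin gene Cldn15 from 24.1 ± 7.48 to 2.76 ± 0.17 CPM (-3.13, SE 0.31). Vwa3a went from 62.8 ± 2.23 to 7.43 ± 1.6 CPM (-3.07, SE 0.23) and Cpne9 from 97.3 ± 2.56 to 13.1 ± 10.5 CPM (-2.89, SE 0.63). Celf3, Frg2f1, Cnga4, Spam1, the mitochondrial RNA polymerase gene Polrmt and Lmln had log2 fold changes between -2.53 and -2.17. Ceacam2 (-2.62) is uncertain because of its close paralog Ceacam1. Without DKO replicate 3 the log2 fold change of Itgb4 was -4.00 and that of Cnga4 went from -2.30 to -3.16, and without DKO replicate 2 that of Cpne9 was -3.51. Among the largest changes, Amigo2, Irx2, Itgb4, Ceacam2, Celf3 and Cnga4 overlap another tested gene, so part of their reads can belong to it. The overlapping genes changed by less in CPM, at most 19.8% of the named gene's change in the same direction (Cnga4). Rnf2 itself was among these 12 falls.

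**Figure D2:**
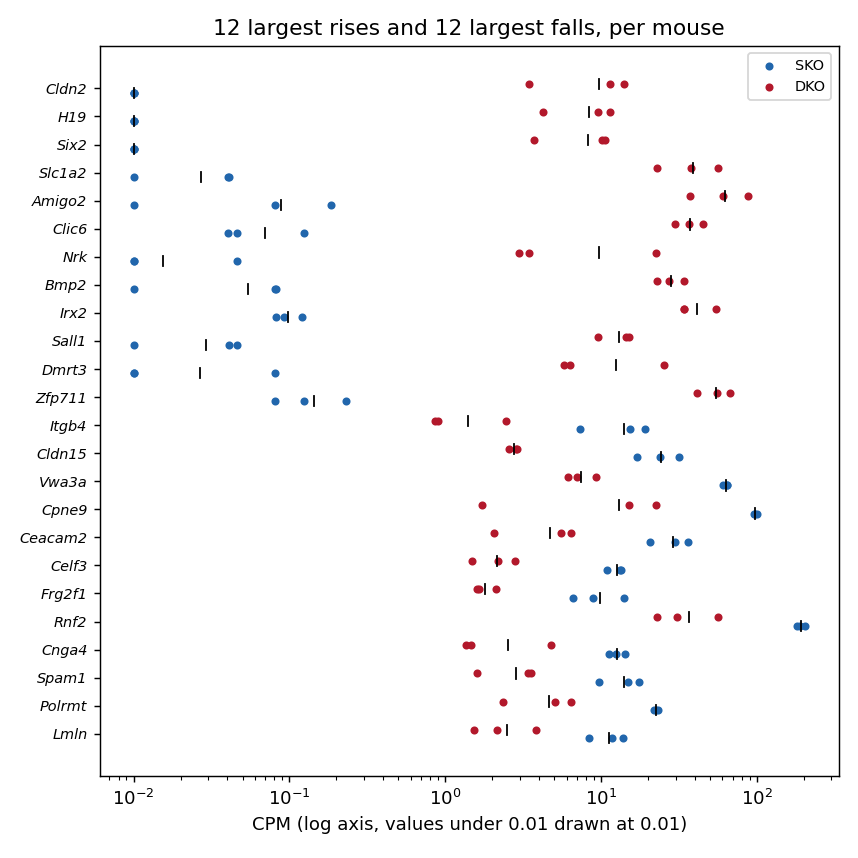
CPM per mouse (log axis, values under 0.01 drawn at 0.01) of the 12 largest rises and 12 largest falls by the fixed rule, with SKO in blue, DKO in red and vertical ticks at the means of 3 mice. No DKO point overlaps the SKO points of the same gene, as the rule required.

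Developmental regulators, the classical Polycomb targets, rose together. Of 23 tested Hox genes, 21 rose and 0 fell, also 21 and 0 adjusted over the list alone, with a median log2 fold change of 4.31 (camera adjusted p = 1.47e-12). The adjusted p was 0.0542 with an estimated correlation. Another 16 of the 39 Hox genes were below the filter and untested. Genes below the filter in SKO enter only with the help of DKO libraries. The share of rises among near-silent members, here and in the other lists, can therefore be in part fixed by the filter. Hoxd13 went from 6.76 ± 0.87 to 95.8 ± 9.79 CPM (log2 fold change 3.82), Hoxd1 from 0.585 to 51.4 ± 18.3 CPM and Hoxd9 from 2.70 to 53.9 ± 13.7 CPM. Of 127 tested developmental transcription factors, 86 rose and 2 fell (96 and 4 adjusted over the list alone), with a median of 3.00 (camera adjusted p = 1.3e-19). This was the only list called with an estimated correlation, at an adjusted p = 0.0181. Another 80 of the 207 factors were below the filter and untested. Irx1 reached 81.2 ± 29.8 CPM from 0.405, the eye and forebrain factor Pax6 reached 57.5 ± 10.8 CPM from 1.45, and Eomes reached 30.1 ± 7.49 CPM from 0.257.

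Secreted signalling factors followed. Of 33 tested ligands and antagonists of the Wnt, BMP, Hedgehog, FGF and Notch pathways, 14 rose and 4 fell (18 and 5 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 0.000435, and adjusted p = 0.0542 with an estimated correlation). Another 32 of the 65 listed were below the filter and untested. Chrdl1, a BMP antagonist, rose from 1.71 ± 1.45 to 124 ± 58.9 CPM (log2 fold change 6.19, SE 0.66, and 6.96 without SKO replicate 2). With the stricter filter the adjusted p of this list was 0.051.

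Imprinted genes of the H3K27me3-dependent class rose: 14 of 17 tested were higher and 0 lower (15 and 0 adjusted over the list alone), with a median of 3.39 (camera adjusted p = 3.53e-09, and adjusted p = 0.0542 with an estimated correlation). Epas1 reached 76.7 ± 6.27 CPM from 3.71, the corepressor gene Tle3 reached 48.6 ± 1.72 CPM from 0.261, Sall3 reached 94.7 ± 13.9 CPM from 2.06 and Smoc1 reached 27.1 ± 9.4 CPM from 0.334. This list shares Sall3, Otx2 and Runx1 with the developmental transcription factors and Bmp7 with the signalling factors. Without SKO replicate 1 the log2 fold change of Tle3 went from 7.48 to 8.71 and that of Smoc1 from 6.31 to 7.21. The noncoding RNA Xist was listed at 0 counts in all 6 libraries, and whether the authors' counting left it out is not given in the sources used here. Canonical imprinted genes were not called as a list (13 of 39 rose, 4 fell, 14 and 4 adjusted over the list alone, median 0.25, camera adjusted p = 0.102, fry adjusted p = 0.000335). Within it Igf2 rose from 3.87 ± 0.45 to 260 ± 121 CPM (log2 fold change 6.07, SE 0.35), Cd81 to 39.4 ± 4.91 CPM, and Magel2 had 3 SKO counts and a ratio of 225 (76.6 to 1094). The log2 fold change of Magel2 went from 7.63 to 8.42 without SKO replicate 1. Igf2 can include reads of the overlapping Igf2os, which gained 1.26 CPM against 256 for Igf2.

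Genes linked to cell death rose as a list: 14 of 24 tested p53 targets and cell death genes were higher and 0 lower (15 and 1 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 0.000701, and adjusted p = 0.0729 with an estimated correlation). The members with the smallest p act on both sides of apoptosis. Pmaip1 and Bcl2l11 encode pro-apoptotic proteins and reached 26.5 ± 11.5 CPM from 0.25 and 242 ± 27 CPM from 87.2, while Bcl2, which encodes an anti-apoptotic protein, reached 12.4 ± 2.41 CPM from 1.61. Without SKO replicate 1 the log2 fold change of Pmaip1 went from 6.68 to 7.58. Of 7 cell cycle inhibitors, 3 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.103, fry adjusted p = 0.026): Cdkn1c rose from 8.85 ± 1.04 to 75.7 ± 24 CPM, Cdkn1a from 5.71 to 12.5 CPM and Cdkn2a from 0.113 to 1.3 CPM. The calls of Cdkn1a and Cdkn2a were lost under some alternatives, with adjusted p up to 0.109 and 0.0559.

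Germline and meiosis genes split. Of 54 tested, 17 rose and 5 fell (18 and 6 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0599, 0.0495 with libraries thinned to the smallest, fry adjusted p = 0.00191). Meioc, needed for meiotic prophase, rose from 3.37 ± 1.48 to 86.3 ± 23.1 CPM (log2 fold change 4.67, SE 0.35). Synaptonemal complex genes Syce1 and Sycp3 reached 30.2 ± 4.37 CPM from 1.86 and 247 ± 86.4 CPM from 27.9, and Mael reached 154 ± 1.42 CPM from 52.1. The level of Sycp3 is uncertain because it overlaps Chpt1, but Chpt1 gained 18.4 CPM against 220 for Sycp3, too little to make the rise. Of 14 tested early zygotic genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone, median 1.09, camera adjusted p = 0.162, fry adjusted p = 0.0331). Its called members Zscan4c, Tcstv1, Pramel16 and Eif1a belong to families of close copies and are uncertain. The calls of Tcstv1, Pramel16 and Eif1a were lost under some alternatives, with adjusted p up to 0.0824, 0.068 and 0.0852.

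Oocyte growth and maternal effect genes fell: 18 of 60 tested were lower and 3 higher (21 and 4 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 3.04e-06). The adjusted p was 0.242 with an estimated correlation. Falls were also more frequent among abundant genes in general, at 18.8% of tested genes over 100 CPM in SKO and 9.66% at 10 to 100 CPM. The list was not compared with genes of like level, so a general fall of abundant transcripts stays open as part of it. Nlrp14 went from 4793 ± 451 to 2659 ± 167 CPM (log2 fold change -0.85, SE 0.15, adjusted p = 0.00266) and the receptor gene Kit from 708 ± 17.5 to 399 ± 47.7 CPM (-0.83, SE 0.15). Against the list, the transcription factor genes Sohlh1 and Sohlh2, active in early oocyte growth, rose by 5.85 (7.20 without SKO replicate 3) and 3.48. Of 45 tested meiotic maturation and spindle genes, 5 fell and 1 rose (2 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00394, and adjusted p = 0.242 with an estimated correlation). Btg4, Wee2 and Pde3a fell by 0.74, 0.67 and 0.67 on the log2 scale, and Pgrmc1 rose by 1.62. The calls of Btg4, Wee2 and Pde3a were lost under some alternatives, with adjusted p up to 0.065, 0.0778 and 0.107. With the stricter filter the adjusted p of the maturation list was 0.0537.

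Chromatin regulators changed in single members. Of 24 tested PRC1 subunit genes, 4 rose and 1, Rnf2, fell, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.845, fry adjusted p = 0.00542). Bcor, a subunit of variant PRC1, rose from 14.1 ± 2.13 to 190 ± 16.4 CPM (log2 fold change 3.75, SE 0.20, adjusted p = 1.48e-06) and Pcgf5 rose by 1.26. Of 12 PRC2 genes, 1 rose and 2 fell, the same adjusted over the list alone (median -0.24, camera adjusted p = 0.141). Epop rose by 2.83, and Eed and Ezh1 fell by 0.63 and 0.61, with adjusted p up to 0.0828 and 0.112 over the alternatives. Of 12 tested DNA methylation genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.685). Camera put this list down although its median of 0.08 and mean of 0.11 were above 0. Uhrf2 rose by 1.81 and Dppa3 by 0.87, and the de novo methylation genes Dnmt3a and Dnmt3l fell by 0.63 and 0.77. The calls of Dppa3, Dnmt3a and Dnmt3l were lost under some alternatives (adjusted p up to 0.119, 0.0642 and 0.0883). Dnmt3a and Dnmt3l overlap Dnmt3aos and Aire and their levels are uncertain, but these fell by 0.405 and 7.65 CPM against 147 and 29.6, too little to make the falls.

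Oxidative phosphorylation and ribosomal protein genes shifted slightly downward. Of 74 tested oxidative phosphorylation genes, 3 fell and 1 rose (0 and 1 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00575, and adjusted p = 0.318 with an estimated correlation). Ndufs7, Ndufb11 and Cox6a1 fell by 1.11, 0.76 and 0.54, and Atp5g3 reached 19.7 ± 2.67 CPM from 6.94 CPM. The calls of Ndufs7, Ndufb11 and Cox6a1 were lost under some alternatives, with adjusted p up to 0.0681, 0.137 and 0.795. Of 69 cytosolic ribosomal protein genes, 3 fell and 1 rose (0 and 0 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00624, and adjusted p = 0.318 with an estimated correlation). The called members Rpl27a, Rpl15 and Rps29 have processed pseudogenes and are uncertain, and the log2 fold change of Rpl27a went from 2.15 to 1.28 without DKO replicate 3 (adjusted p = 0.0645). The calls of Rpl15 and Rps29 were lost under some alternatives, with adjusted p up to 0.0848 and 0.119. The ribosomal list had an adjusted p of 0.0625 without DKO replicate 3, and with the stricter filter the adjusted p was 0.0786 for oxidative phosphorylation and 0.0537 for ribosomal proteins. Fry gave an adjusted p = 0.129 for both. Removing the trend with GC content and gene length brought the medians to -0.04 and 0.02 and ended both calls (adjusted p = 0.598 and 0.47).

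Markers of other ovarian cells moved with the genotype in part. Of 21 tested granulosa and cumulus markers, 9 rose and 1 fell, the same adjusted over the list alone, with a median of 0.92 (camera adjusted p = 0.00156, and adjusted p = 0.0729 with an estimated correlation). Ptgs2 rose from 3.80 ± 0.50 to 87.1 ± 8.93 CPM and the follicle-stimulating hormone receptor gene Fshr from 0.506 ± 0.04 to 30.7 ± 2.54 CPM. Gata4, which is also among the developmental transcription factors, and Cyp11a1 rose by 1.31 and 1.34. The most abundant markers were Serpine2 (388 ± 49.5 CPM in DKO, 373 ± 39.8 in SKO), Gata4 (130 ± 2.67 and 52.4 ± 4.79) and Nr5a2 (117 ± 15.5 and 79.2 ± 9.98). Of 16 tested theca, stroma and endothelium markers, 5 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.93, camera adjusted p = 0.107, fry adjusted p = 0.000376). Pdgfra, Col1a1 and Dcn rose by 2.69, 4.16 and 2.71, and Upk3b fell by 3.05. The most abundant were Myh11 (137 ± 70.6 and 211 ± 13.5 CPM), Pecam1 (61 ± 7.75 and 110 ± 17.3 CPM) and Tek (32.8 ± 3.09 and 25.5 ± 4.35 CPM). Of 7 tested blood and immune markers, 3 rose and 0 fell, the same adjusted over the list alone (median 0.47, camera adjusted p = 0.265, fry adjusted p = 0.0147). The adjusted p was 0.0381 with the DESeq2 Wald test and 0.0349 without a filter. C1qb rose from 22.9 ± 2.89 to 58.8 ± 4.63 CPM and H2-Aa from 3.48 to 10.8 CPM (adjusted p up to 0.0743 over the alternatives). These 2 and Cd68 (2.47 ± 1.88 and 2.02 ± 1.04 CPM) were the most abundant by the mean of both genotypes.

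**Figure D3:**
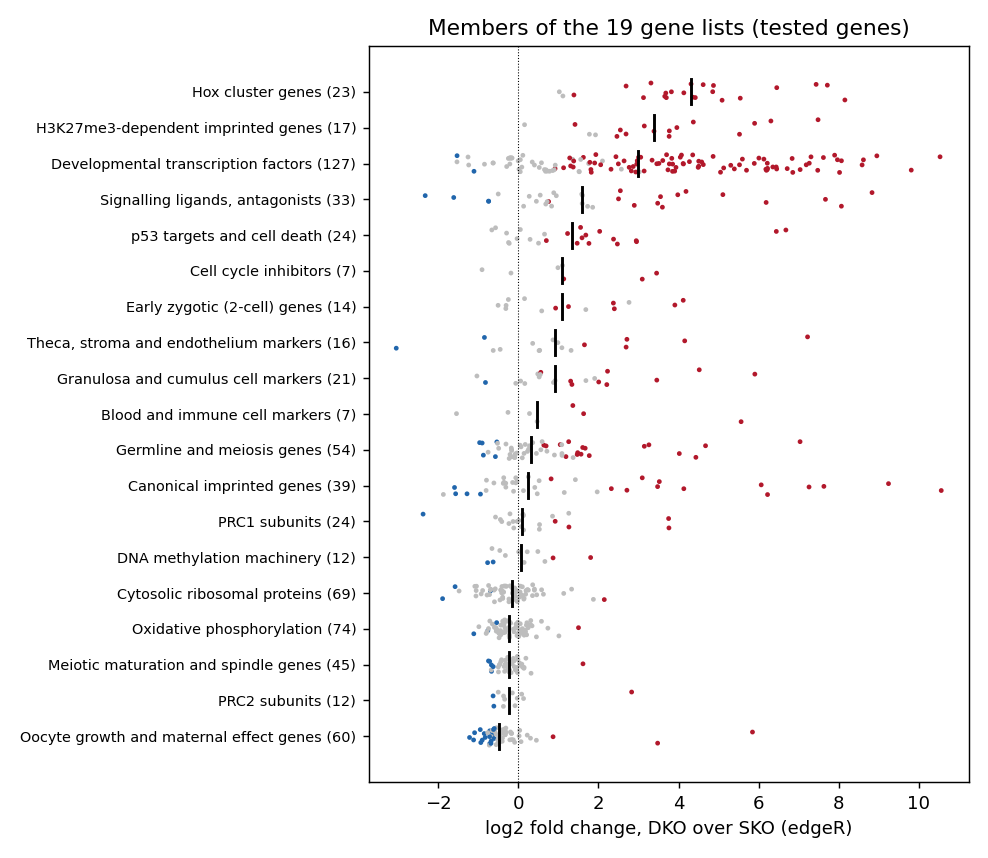
Log2 fold change (DKO over SKO, edgeR) of the tested members of the 19 gene lists, with the number tested in parentheses and lists ordered by their median (black tick). Red members rose, blue members fell and grey members were not called. Hox genes have a median of 4.31 and oocyte growth and maternal effect genes a median of -0.49.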

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

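Of the alternatives, 18 were fixed before the data were examined and 3 were chosen after seeing them (thinning, the GC and length trend, near-identical genes counted once). Counting near-identical genes once reuses the fold changes, and under the other alternatives fitted per gene no called gene was called in the opposite direction, and 0 named genes reversed. Of 92 named genes with alternatives, 71 kept their call in all of them and 21 lost it in at least 1. The Rnf2 log2 fold change stayed between -2.83 and -2.14. Library totals alone gave 596 falls (245 of at least 2-fold). The stricter filter, which tests 10209 genes, gave 1666 rises (1316 of at least 2-fold), 266 falls of at least 2-fold and 6 called lists. An adjusted p under 0.01 gave 1581 rises and 311 falls (208 of at least 2-fold). Removing the GC and length trend gave 2500 rises and 1933 falls. An estimated correlation left 1 called list, and fry called 15, of which 13 rose. The cause of the moves under library totals and GC removal was not tested. Leaving out each library in turn gave 1952 to 2704 rises, 434 to 1501 falls, 1897 to 2363 rises of at least 2-fold, 284 to 655 falls of at least 2-fold (655 without DKO replicate 2) and 9 to 10 called lists. Fewer samples enter these fits. Counting overlapping near-identical genes once gave 2535 rises and 1094 falls, and thinning gave 2451 and 1035. With the replicate number as a block there were 2651 rises and 1364 falls, of which 2451 and 1034 were also called without it. The labels do not say that the numbers pair mice. Deviations of same-numbered samples correlated at 0.139, 0.0773 and 0.0479, and every sample correlated best with its own number, a hint from the data and not the design. Of the 10 splits of the 6 samples into groups of 3, the real one alone (1 split in each case) gave as many calls: 2567 rises, 1100 falls, 2267 and 426 of at least 2-fold and 10 lists, against at most 1, 1, 1, 1 and 8 in the other splits. With 10 splits no share can fall under 0.1. Every other split mixes the genotypes, so the genotype difference enters the spread within its groups and few called genes were bound to follow. The contrast in called genes therefore does not measure chance. Depth limits genes near 3 counts (0.113 to 0.193 CPM).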

Other observations

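The tests of X-linked genes, of granulosa RNA, and of GC content and length were chosen after the results were seen. The gene families and chromosomes below were also scanned after seeing the data. Fisher's exact test, the odds ratios and the bootstrap intervals below treat genes as independent units. They ignore correlation between genes of the same libraries and do not measure variation between mice.

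Families of genes with a shared symbol root and at least 8 tested members were scanned with overlapping near-identical genes counted once (259 families, one-sided Fisher's exact test against 17.1% rises and 7.43% falls among all genes, Benjamini-Hochberg adjustment). Genes below the filter in SKO entered only with the help of DKO libraries, which can raise the share of rises in a family. Rises were over-represented in 10 families. They included Hoxa (9 of 9, adjusted p = 3.27e-05), Sox transcription factors (11 of 16, adjusted p = 0.000892), cadherins of the Cdh root (11 of 17, adjusted p = 0.00142), Wnt receptors of the Fzd root (7 of 9, adjusted p = 0.00728), myosin heavy chains of the Myh root (8 of 13, adjusted p = 0.0195) and keratins of the Krt root (10 of 20, adjusted p = 0.0276). Falls were over-represented in 1 family, the F-box genes of the Fbxw root (11 of 22, adjusted p = 3.07e-05). Of these, 13 lie side by side on chromosome 9 (109139454 to 109790660, GRCm38), where 10 fell and 0 rose, against 1 of 9 elsewhere. Fbxw13 went from 208 to 65.5 CPM (log2 fold change -1.66, SE 0.17, edgeR adjusted p = 9.66e-05) and Fbxw21 from 536 to 247 CPM. The neighbours Fbxw14, Fbxw27 and Fbxw28 were not called. These paralogs can share reads and are uncertain.

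All 14 tested protocadherin alpha genes (chromosome 18, 36930285 to 37188897) rose, from 3.23 to 3.57 CPM in SKO to 23.2 to 29.1 CPM in DKO, and all 22 gamma genes (37661775 to 37841873) rose from 0.208 to 0.224 CPM to 1.38 to 2.46 CPM. The 14 alpha genes held 10 distinct sets of counts and the 22 gamma genes 15, so they are not independent rises. The gamma genes lay under the filter level of 0.413 CPM in SKO and entered only with the help of DKO libraries. Their rises are therefore in part fixed by the filter. On chromosome 18, which holds these clusters, 113 of 407 tested genes rose (27.8%), and with overlapping near-identical genes counted once 86 of 380 (22.6%, odds ratio 1.43, 95% interval 1.11 to 1.83, adjusted p = 0.0284). Without the 40 genes of the protocadherin clusters, 76 of 367 rose (20.7% against 17% elsewhere, Fisher's exact test, odds ratio 1.28, 95% interval 0.974 to 1.65, adjusted p = 0.246), so much of the excess came from the clusters and a smaller one stays open. Rises were fewer than elsewhere on chromosomes 8 (12.4%, odds ratio 0.662, adjusted p = 0.00109), 17 (12.3%, odds ratio 0.658, adjusted p = 0.00167) and 5 (13.5%, odds ratio 0.733, adjusted p = 0.00607). Falls were fewer on chromosome 2 (4.68%, Fisher's exact test, adjusted p = 0.00109) and more frequent on chromosome 5 (9.83%, adjusted p = 0.0244). The shares of these chromosomes and of chromosome 18 were not compared among genes of like level. Both rises and falls vary steeply with the SKO level. Level and entry by the filter therefore stay open as a source of these differences.

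X-linked genes rose more often than autosomal genes: 151 of 542 tested (27.9%) against 2413 of 14289 (16.9%; Fisher's exact test, odds ratio 1.90, adjusted p = 1.71e-08), and 3.51% fell against 7.57%. The excess stayed within 10 strata of the SKO mean, where the common odds ratio was 1.69 (95% interval 1.36 to 2.10). It was 1.79 within strata of the average over both genotypes, and counting overlapping near-identical genes once gave 1.70 (1.37 to 2.11). Rises vary steeply at low level (98.9% of genes at up to 0.1 CPM in SKO, 37.2% at 0.1 to 1 CPM). Genes that entered only with the help of DKO libraries were kept. Level within strata and entry by the filter therefore stay open as part of the excess. No single library carried the X excess, as the lowest lower bound over 6 fits without a library was 1.23. Among genes of at least 30 CPM on average, the median log2 fold change of 169 X-linked genes exceeded that of 5202 autosomal genes by 0.27 (bootstrap 95% interval 0.15 to 0.38), above 0 but under the 0.5 set for a shift of the whole chromosome. A smaller general shift stays open, and a stronger response of X-linked genes to Rnf2 deletion is a hypothesis that was not tested otherwise. The intervals take genes as units, so correlated changes of X-linked genes would make them too narrow.

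The rise of granulosa and cumulus markers may come from somatic RNA or from the oocytes. The labels say granulosa cells were removed by pipetting. Granulosa RNA would raise all of its abundant transcripts, but over the 22 markers under 5 CPM in SKO other than Fshr the median gain was 0.274 CPM (bootstrap 95% interval 0.0575 to 1.29), against 30.2 CPM for Fshr, and 17 gained less than 3.02 CPM. Inha measured 3.02 CPM in DKO and 2.15 in SKO, Amh 0.795 and 1.63, and Vim 0.281 and 0.0291, while Ptgs2 measured 87.1 and 3.80, Has2 8.78 and 1.87, Wt1 5.29 and 0.476, Inhba 5.44 and 1.35, and Gja1 4.39 and 0.952. The markers thus did not rise together. Their levels in granulosa cells were not measured here, and some were near 0 CPM in both genotypes (Ptx3 0 in both, Tnfaip6 0 in DKO and 0.0134 in SKO). The small median gain therefore cannot decide how much of the rise came from granulosa RNA. That source stays open, and expression of single markers by DKO oocytes stays a hypothesis.

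The falls of 3 lists were set against GC content and gene length. The median length was 1937 bases for the oocyte list, 744.5 for oxidative phosphorylation and 862 for ribosomal proteins, against 3283 for all tested genes. With the trend removed, the oocyte median went from -0.49 to -0.43 and the list kept its call (camera adjusted p = 3.67e-05), which argues against the trend as its whole cause. The other 2 medians went from -0.22 to -0.042 and from -0.15 to 0.0191, and both lists lost their calls because the shift itself shrank. Their genes are short, and removing a length trend also takes out a real shift of short genes. A technical trend and an effect of genotype on such genes therefore cannot be told apart. A scaling moves all genes alike, so the gap of the oocyte median to that of all genes hardly moved (-0.53 to -0.51 over 4 scalings), and the adjusted p = 0.242 with an estimated correlation keeps the list open. A match of the oocyte list on expression level was not run.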
